A study of Drosophila melanogaster with 20 samples.

How the data were processed

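Messenger RNA from whole bodies of 2-day-old male flies was sequenced with a stranded library kit, 1 library per line and treatment, each from 10 pooled flies. The 10 lines belong to the Drosophila Genetic Reference Panel (DGRP), a set of inbred lines derived from wild-caught flies. Per the labels, 5 lines were classed as beneficial (RAL69, RAL93, RAL359, RAL387 and RAL409) and 5 as detrimental (RAL195, RAL304, RAL335, RAL737 and RAL819) by their preconditioning outcome. Each line gave a library without heat shock and a library from flies frozen straight after 30 minutes at 35 ± 1 °C.

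The authors deposited raw counts, as whole-number counts per FlyBase gene, for 17807 genes in 20 libraries. The submitters' processing notes name genome build BDGP6, Bowtie2 2.2.9, SAMtools 1.12 and DESeq2 1.28.1, without saying which step each served. The counting tool and the annotation were not stated. The authors also deposited 2 result tables that compare the classes, with and without heat shock, from which line RAL409 was left out. Per the file headers, these hold log2 ratios of beneficial to detrimental lines with standard errors, on the log2 scale. Their p-value columns, also deposited by the authors, hold unadjusted and adjusted values, and the filters behind them were not stated. The names of both tables point to a threshold of 0.1, and counts at 0.1 stand beside those at 0.05.

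Gene symbols and positions were taken from the BDGP6 annotation of Ensembl release 115, whose release may differ from the authors'. In it 17710 identifiers had a match and 97 had none. Total counts per library ran from 18.4 to 33.7 M. These totals set the counting error only, and 1 pool per line and treatment gave no measure of the spread between pools of a line.

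Line was the unit of replication. Line RAL409 was left out of every main test, as the study did, which left 18 libraries from 9 lines, 4 beneficial and 5 detrimental. Tests used R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by trimmed mean of M values (TMM), and quasi-likelihood F tests were run. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The classes were compared within each treatment on the 9 libraries of that treatment. Heat shock was compared with none in a single fit of 18 libraries with 1 coefficient per group, over all lines, within each class, and as the difference between the responses of the classes. No block for line was stated by the study and none was used in these fits. Because each line gave a library under both treatments, a fit with line as a block was also run, and its values stand beside the results it changed. Normalised read counts (CPM) are counts divided by the TMM-scaled library total in M, where M stands for 1e+06.

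For genes named one by one, a rule was fixed. It took up to 10 genes per direction with the largest change among those past the threshold, with a mean CPM of at least 1 and either no overlap between the classes or the same direction in every line. It also took up to 5 genes per direction with the smallest p, and up to 4 members of each gene list with the smallest p among those past the threshold. A set of 30 heat shock, endoplasmic reticulum (ER) stress and histone methylation genes was named whatever its values. The 5 genes with the smallest adjusted p in each of the authors' tables completed the rule. Genes outside it are marked where they appear.

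Each of 33 gene lists with 5 or more tested members was compared with the other genes by camera in limma 3.58.1 with its preset correlation between genes, and adjusted over lists. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move on balance in the same direction without comparing them with other genes, were run beside it. A score per library, the mean log2 CPM over a list's tested members with a prior count of 2, was compared between classes by a two-sided exact permutation test over the 126 splits of 9 lines, whose smallest possible p is 0.00794. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

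The alternatives were DESeq2 1.42.0, limma-voom with and without line as a random effect, line as a block, other scaling factors and count filters, a looser threshold of 0.1, robust dispersions, RAL409 included, and each line left out in turn. Scaling by library totals only, and DESeq2 on every row with a count, were added after the data had been seen, as were intervals for the difference between responses with line as a block. The tests were tried on simulated counts with the means, dispersions and library sizes of these libraries, in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. For the class comparison without heat shock (13770 genes tested) edgeR recovered 26.9%, 67.2% and 81.8% of them, with 8 false calls, and DESeq2 made 48 false calls. For the class comparison under heat shock (13877 genes) edgeR recovered 14.9%, 56.7% and 90.9% with 4 false calls, and DESeq2 made 44. For heat shock over all lines (14270 genes) edgeR recovered 62.7%, 86.6% and 100%, and for the difference between the responses of the classes 10.4%, 52.2% and 90.9%. Simulated libraries were drawn independently, so both libraries of a line shared no line effect, unlike the real ones. Recovery in the comparisons across treatments may therefore differ in the real data. In each comparison, recovery and false calls may also differ where fewer genes than the 200 planted are changed.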

Results

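Whole male flies of 10 DGRP lines were profiled with and without a heat shock of 30 minutes at 35 ± 1 °C, a temperature 10 °C above that of rearing. The lines had been sorted into classes of 5 by whether preconditioning, an earlier mild stress, was followed by a beneficial or a detrimental outcome. The beneficial lines gave 24.7 to 27.9 M counts per library without heat shock and 28.2 to 33.7 M with it (n = 4 lines each, RAL409 left out). The detrimental lines gave 22.8 to 28.4 M and 18.4 to 28.8 M (n = 5 lines each). Treatment separated the libraries along the first principal component, which held 20.65% of the variance. Line RAL409 lay apart on the second component (11.19% of the variance), at −59.0 without and −55.8 with heat shock, while the other libraries lay between −21.5 and 28.2. After the mean of each class under each treatment was removed, both libraries of a line resembled each other in 9 of 9 lines. Correlations across genes were 0.543 to 0.805, against at most 0.119 between lines. Removing these means lowers the correlations between lines of a class by construction, so part of that contrast is built in. The labels give no sequencing batch or date.

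The comparison of heat shock with none over all lines asks which transcripts the treatment changed within its 30 minutes. Transcripts of the inducible Hsp70 chaperones, which refold damaged proteins, rose by a log2 of 10.45 ± 0.26 (SE, n = 9 lines) when the 6 gene copies were summed. Single copies rose by 10.39 to 10.53, but reads of such near-identical copies can be assigned to either, so the sum is the firmer value. Hsp68 (FBgn0001230, BDGP6 3R 24055080 to 24057310) rose from 63.7 ± 6.71 to 8423 ± 1170 CPM (SD), a log2 change of 7.03 ± 0.11. The small heat shock proteins rose likewise, Hsp23 by 7.02 ± 0.13, Hsp26 from 71.8 ± 10.7 to 6745 ± 682 CPM and Hsp27 by 5.82 ± 0.13. The co-chaperones DnaJ-1 (FBgn0263106, 3L 5750029 to 5752189) and stv rose by 4.38 ± 0.06 and 4.28 ± 0.08, and the Hsp90 gene Hsp83 by 3.70 ± 0.08. Of 27 tested chaperone genes, 26 rose, over all genes and adjusted over the list alone, in edgeR. CG4456 did not pass, at 15.0 CPM without and 16.1 CPM with heat shock (log2 0.10 ± 0.10, adjusted p = 0.622). Hsp22, listed at 0 in all 20 libraries, overlaps most of CG4456 on the same strand, and how reads in both were counted was not stated, so neither value measures its gene safely. Chaperone genes took 0.426 ± 0.0259% of counts in beneficial and 0.411 ± 0.0101% in detrimental lines without heat shock, and 8.48 ± 0.301% and 9.15 ± 1.20% with it (SD). The list passed camera (adjusted p = 1.89e-09 with an estimated correlation). The noncoding RNA lncRNA:alphagamma-element:CR32865, transcribed at 3R 12475336 to 12478267, rose by 9.35 ± 0.53, from 0.314 to 204 CPM.

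**Figure D1:**
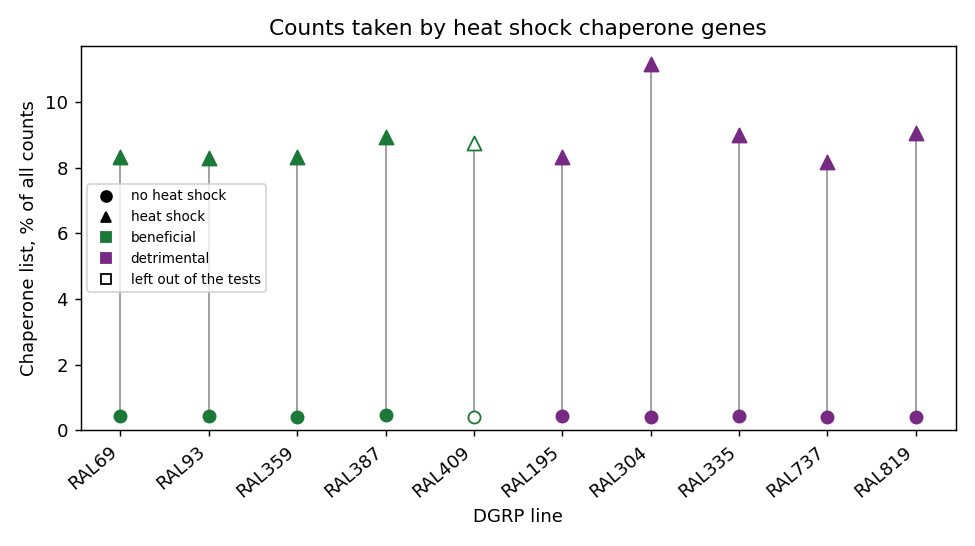
Share of all counts taken by the heat shock chaperone genes (y axis, percent) in each line (x axis), without heat shock (circles) and with it (triangles). Colours give the class, open symbols the line left out of the main tests, and each point is 1 library. RAL304 lay highest with heat shock, at 11.2%.

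Of the genes for protein folding in the ER and its unfolded protein response, 9 of 36 rose and 5 fell. Adjusted over the list alone 10 rose and 7 fell. The ER chaperone Hsc70-3, known as BiP, rose by 1.62 ± 0.12, the kinase PEK (PERK) by 1.20 ± 0.09, the transcription factor Xbp1 by 0.89 ± 0.07 and the chaperone Gp93 by 0.85 ± 0.09 (n = 9 lines). The sensor Ire1 fell by 0.22 on the log2 scale (adjusted p = 0.0216), a call lost without RAL69, RAL387 or RAL304 (adjusted p = 0.0648, 0.064 and 0.0646) and with RAL409 included (−0.16, adjusted p = 0.186). Atf6, another sensor, stood at −0.34 ± 0.15 (adjusted p = 0.152), and with line as a block at −0.35 ± 0.07 (adjusted p = 0.00153). crc, the fly ATF4, stood at −0.01 ± 0.08. As a list these genes did not pass camera (adjusted p = 0.449), and their median (−0.01) and mean (0.08) differed in sign. Genes of redox defence did pass (adjusted p = 0.000382, and adjusted p = 0.167 with an estimated correlation), with 5 of 20 higher and none lower, also adjusted over the list alone. With line as a block 8 rose and 1 fell. Among them were Gclm, for glutathione synthesis (1.84 ± 0.12), the autophagy receptor ref(2)P (1.74 ± 0.10), the reductase Trxr1 (0.87 ± 0.04) and cnc, the fly Nrf2 (0.35 ± 0.05). Of the glutathione S-transferases, which detoxify electrophiles, 5 of 36 rose and 1 fell (6 and 1 adjusted over the list alone, 12 and 5 with line as a block). GstE1 rose by 2.12 ± 0.32.

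Genes that write, erase or bind histone marks changed in both directions. Among histone methyltransferases and their partners 4 of 36 rose and 10 fell (7 and 12 adjusted over the list alone, 7 and 15 with line as a block). E(z), the H3K27 methyltransferase, fell by 0.35 on the log2 scale and egg, an H3K9 methyltransferase, by 0.38. The arginine methyltransferase Art4 fell by 0.83 and csul by 0.56 (n = 9 lines each, lower in each of them). trx, the founding Trithorax gene, rose by 0.31 ± 0.09 (adjusted p = 0.0153), a call lost on scaling by library totals (0.12, adjusted p = 0.318). Su(var)3-9, G9a and ash1 stood at 0.13 ± 0.17, 0.06 ± 0.06 and 0.14 ± 0.08 and did not pass. Among histone demethylases Kdm2 (0.83 ± 0.11), Kdm5 (0.45 ± 0.08) and Kdm3 (0.40 ± 0.10) rose and Su(var)3-3 fell by 0.27, which made 3 and 1 of 11 (3 and 4 adjusted over the list alone, 4 and 5 with line as a block). The demethylase Utx stood at −0.18 ± 0.07 (adjusted p = 0.101, and 0.00406 with line as a block). Kdm4A stood at −0.09 ± 0.16 and Kdm4B at 0.09 ± 0.09. Of Polycomb repressive complex 1 and the PHO complex 1 of 11 rose (phol, 0.51 ± 0.06) and 4 fell, among them ph-d by 0.43 and ph-p by 0.39 (2 and 5 adjusted over the list alone). Of acetyltransferases and deacetylases 2 of 19 rose, with Sirt1 at 1.66 ± 0.09, and 6 fell, with HDAC1 at −1.16 ± 0.09 and Gcn5 at −0.73 ± 0.08. The last counts were the same adjusted over the list alone. None of these 4 lists passed camera (adjusted p = 0.297 to 0.746).

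Mitochondrial ribosomal proteins fell in 15 of 71 cases and rose in none (19 lower adjusted over the list alone, 31 with line as a block). mRpL52 fell by 0.43 and mRpS30 by 0.29 on the log2 scale. The list passed camera (median −0.15, adjusted p = 0.00143), but not with a correlation estimated from the data (adjusted p = 0.998). Of 13 tested eggshell and female germline genes 3 rose, also adjusted over the list alone, though the flies were male. The chorion gene Cp18 rose from 0.684 ± 0.242 to 17.6 ± 2.54 CPM. Cp19, also a chorion gene, rose by 3.34 ± 0.57, but only from 0.0516 to 0.607 CPM, and Cp18 lies upstream of it on the same strand. The third was fs(1)M3 (1.25 ± 0.41). This list passed camera (adjusted p = 0.0057, and adjusted p = 0.0486 with an estimated correlation, 0.204 with line as a block). One list held immediate early genes and genes of the JNK pathway, which relays stress signals. In it puc rose by 0.84 ± 0.09, Jra by 0.50 ± 0.06 and kay by 0.50 ± 0.07, while cbt fell by 0.72. The list's counts were 4 of 22 higher and 3 lower (5 and 3 adjusted over the list alone, 8 and 5 with line as a block). The triglyceride lipase bmm rose by 1.01 ± 0.07 and CG5966, a predicted lipase, by 2.93 ± 0.20. Of 18 lipid genes 4 rose and 1 fell (the same adjusted over the list alone, 6 and 6 with line as a block). Among insulin and TOR genes InR rose by 0.85 ± 0.16, and sug fell by 1.26. None of the accessory gland, testis or muscle markers passed, of 49, 33 and 25 tested in edgeR, and adjusted over the list alone 0 passed as well. With line as a block 8 testis markers rose.

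The largest falls among genes lower in each of the 9 lines were those of AANATL3, an N-acetyltransferase (−3.47 ± 0.37), of repo, the glial transcription factor (−2.20 ± 0.11), and of CG13607 (−2.16 ± 0.25). GATAe, which specifies the gut (−1.91 ± 0.09), pirk, an inhibitor of the Imd immune pathway (−1.79 ± 0.22), and odd (−1.64 ± 0.10) also fell. Of 14270 genes tested in edgeR 2555 passed, 1183 higher and 1372 lower, and 344 and 98 of them changed at least 2-fold. With line as a block 5032 passed, 2333 higher and 2699 lower, among them all 2555. Under scaling by library totals the median gene stood at −0.19, and 14.1% of 4932 called genes were higher against 46.3% of the 2555, so changes are relative to the median gene.

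Within each class the comparison asks what the same treatment did to lines of that outcome. In beneficial lines 1089 genes passed in edgeR, 609 higher and 480 lower (n = 4 lines), and in detrimental lines 1422, 660 of them lower (n = 5 lines). Hsp68 rose by 6.91 in beneficial and by 7.15 in detrimental lines, DnaJ-1 by 4.36 and 4.40, and PEK by 1.22 and 1.17. Of the genes that rose 557 did so in both classes, where 32.5 would be shared by chance, of those that fell 395 (22.2 by chance), and 0 moved in opposite directions. With line as a block 2767 genes (1307 higher, 1460 lower) and 3265 genes (1466 higher, 1799 lower) passed, and on library totals 446 higher and 1732 lower in beneficial and 493 and 2950 in detrimental lines, so which direction held more genes depended on the setting. With the block Ire1, Atf6 and trx gained a call in each class (adjusted p = 0.0131, 0.0356 and 0.0172 in beneficial, 0.0456, 0.012 and 0.0152 in detrimental lines) and Utx in detrimental lines (0.00652). The beneficial count fell whichever beneficial line was left out, to 682 without RAL359, 628 without RAL387, 751 without RAL69 and 774 without RAL93. The heat shock libraries of RAL359 and RAL387 had trends of 0.15 and −0.10 on the log2 scale per doubling of exonic length. Whether these trends play a part in the drops was not tested. The detrimental count was 936 without RAL335. Chaperones, redox defence, mitochondrial ribosomal proteins and eggshell genes passed camera in each class. With an estimated correlation the chaperones kept their call in each class, the eggshell genes in beneficial lines (adjusted p = 0.0363, but 0.163 with line as a block) but not in detrimental lines (adjusted p = 0.0885, and 0.319 with the block), and the remaining lists in neither (adjusted p = 0.15 to 0.993).

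**Figure D2:**
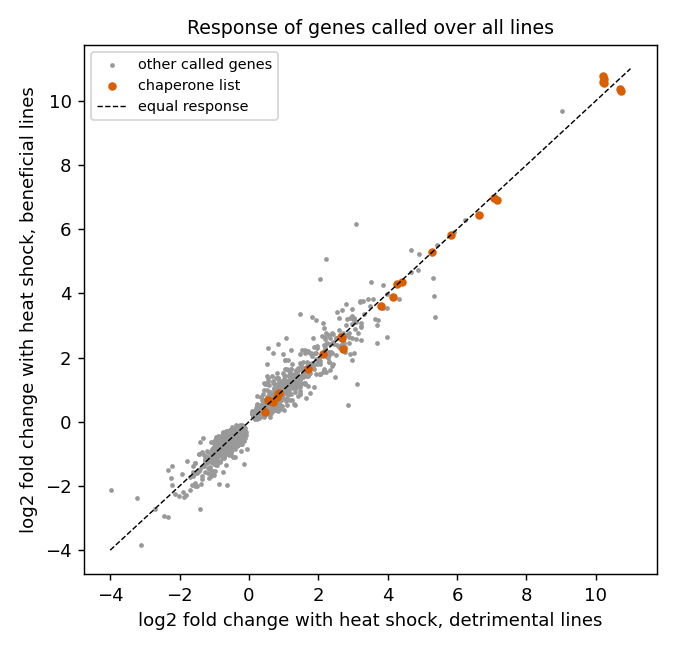
Heat shock response (log2 fold change with heat shock against none) of the 2555 genes called over all lines, in detrimental lines (x axis) and in beneficial lines (y axis). Each point is a gene, with chaperone list genes in orange, and the dashed line marks equal responses. The slope through 0 was 0.998 across these genes.

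The study's question rests on whether the classes answer heat shock differently. Across the 2555 called genes the responses of the classes had a Pearson r of 0.974 across genes, which are not independent replicates. These genes had been picked for a response in the same lines, and over all genes tested r was 0.888. As beneficial minus detrimental responses, Hsp68 differed by −0.24 (95% interval −0.60 to 0.12), DnaJ-1 by −0.05 (−0.26 to 0.17), Hsc70-3 by −0.15 (−0.66 to 0.37), E(z) by 0.05 (−0.21 to 0.30) and trx by 0.06 (−0.30 to 0.42). For the summed Hsp70 copies the difference was 0.08 ± 0.34. The chaperone score rose by 4.68 ± 0.10 in beneficial and by 4.70 ± 0.20 in detrimental lines (SD, n = 4 and 5, exact permutation p = 0.865, adjusted p = 0.997). In edgeR 0 of 14270 genes passed, with 42 at an unadjusted p under 0.05. DESeq2 gave 0 with 40, limma-voom 0 with 38, and edgeR with line as a block 0 with 338. Had no response differed, a share near 0.05 of the genes would lie there. All these counts are smaller, and smallest in the fits without a block, which count the spread between lines as error. Low counts are thus no evidence of equal responses. The 95% interval of the difference reached 0.39 to either side of its estimate for the median of the 2555 genes, and 0.28 with line as a block, so smaller differences were not excluded. With the block that of Hsp68 ran from −0.49 to −0.00 (adjusted p = 1). By camera 8 lists passed, each with a median between −0.19 and 0.04, and 0 passed with an estimated correlation (adjusted p = 0.697 to 0.914).

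The comparison of the classes without heat shock asks whether unstressed flies of the classes differ. An adjusted p under 0.05 was given by the authors to 21 genes, 12 higher and 9 lower in beneficial lines (28 genes under 0.1). CG12917 (FBgn0033490, 2R 10137656 to 10139267) stood at 12.5 ± 0.915 CPM in beneficial and 24.4 ± 4.46 CPM in detrimental lines (SD, n = 4 and 5), with a log2 ratio of −0.96 ± 0.14 here and −0.97 in the authors' table. CG11912 stood at 29.0 ± 9.69 against 10.1 ± 2.66 CPM and CG3348 at 51.1 ± 8.04 against 24.5 ± 6.23 CPM. CG15263 (FBgn0028853, 2L 15285000 to 15286047), with the highest ratio of these (8.27 ± 1.34 in the authors' table), was read mainly in RAL93 and RAL69, at 8.53 and 3.24 CPM. CR30409 stood at 1.21 in the authors' table and at 0.54 ± 0.22 here. All 19 of the 21 genes tested here kept the sign and had an unadjusted p under 0.05, and 18 did not overlap between classes. The authors had picked these genes on the same lines, so such agreement was likely from the start and adds no separate evidence.

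In edgeR 0 of 13770 genes passed, with 576 at an unadjusted p under 0.05 and a smallest adjusted p of 0.581 (CG12917). limma-voom gave 0 with 556, and DESeq2 gave 17, 9 higher and 8 lower. Of the heat shock and ER genes named in advance, Hsp68 differed by 0.05 ± 0.11, Hsc70-3 by 0.07 ± 0.09 and Xbp1 by 0.04 ± 0.09, and of the histone genes E(z) differed by 0.07 ± 0.08 and trx by −0.19 ± 0.08 (adjusted p = 0.999 for each). By camera 11 lists passed, and with an estimated correlation 0 did. The 15 tested mitochondrially encoded genes were each lower in beneficial lines (median −0.59, adjusted p = 4.65e-08, but adjusted p = 0.221 with an estimated correlation). Hemocyte markers (blood cells, −0.29), antimicrobial peptides (−0.46), Turandot and JAK-STAT genes (−0.23) and insulin and TOR genes (−0.04) were lower in the median, and ER protein folding (0.10) and gut digestive enzymes (0.27) higher, each with adjusted p = 0.221 with an estimated correlation. Accessory gland markers (0.15), respiratory chain genes (0.06), proteasome genes (0.06) and neuronal markers (−0.12) completed the 11 (adjusted p = 0.739 to 0.764 with an estimated correlation). Adjusted over the list alone, Tep1 of the Turandot and JAK-STAT list was lower, as was 1 insulin and TOR gene. By line scores 0 lists passed. ER protein folding came nearest, with a score 0.10 higher on the log2 scale (n = 4 and 5 lines, exact permutation p = 0.00794, adjusted p = 0.131), with each beneficial line above each detrimental line. Mitochondrially encoded genes stood at 7.08 ± 0.26 against 7.59 ± 0.19 log2 CPM (SD) with the same exact permutation p and adjusted p. Each of the 4 beneficial lines lay below each detrimental line. RAL409, the beneficial line left out, stood at 7.69 for this list, above the detrimental mean. The share of all counts taken by mitochondrially encoded genes, 4.17 ± 0.963% against 5.01 ± 1.59% (SD), overlapped between classes. The histone methyltransferase score was 4.51 ± 0.05 against 4.54 ± 0.04 (exact permutation p = 0.373, adjusted p = 0.76).

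**Figure D3:**
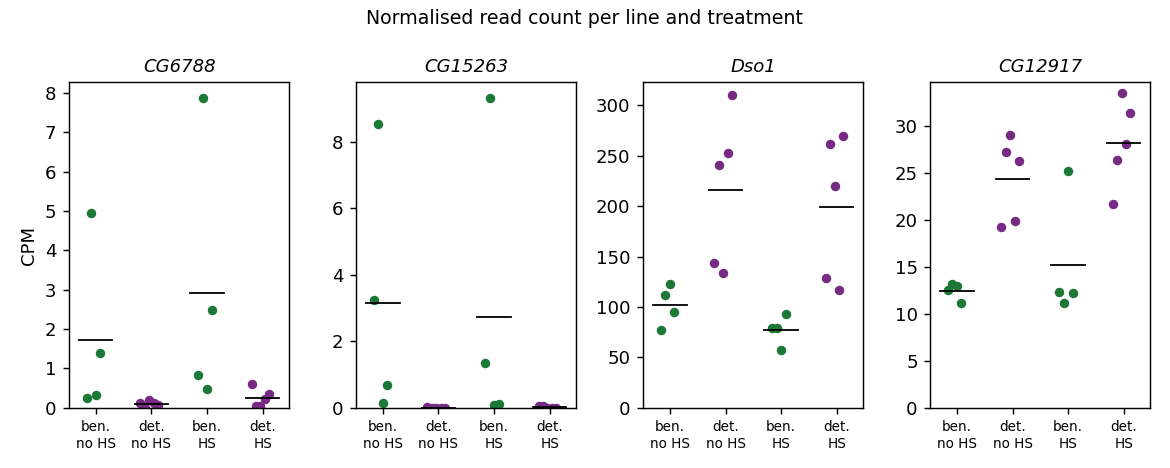
Normalised read count (CPM, y axis) of 4 genes from the authors' tables by class and treatment (x axis; ben. beneficial, det. detrimental, HS heat shock), with 1 point per line, RAL409 left out, and a bar at the mean. Among the 9 lines drawn CG6788 and CG15263 were highest in RAL93, at 7.88 and 9.32 CPM with heat shock.

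The comparison under heat shock asks the same of stressed flies. The authors gave an adjusted p under 0.05 to 15 genes, 5 higher and 10 lower in beneficial lines (26 genes under 0.1). CG10962 (FBgn0030073, X 8972908 to 8974255) stood at 1.19 ± 0.282 against 4.23 ± 1.05 CPM (SD, n = 4 and 5), a log2 ratio of −1.83 ± 0.27. The odorant binding protein gene Obp99b stood at 14.4 ± 6.72 against 66.7 ± 35.9 CPM, and Dso1, a gene of the humoral immune response, at 77.0 ± 14.6 against 199 ± 72.3 CPM. The antimicrobial peptide gene DptB, chosen after its values were seen, stood at 0.995 ± 0.409 against 3.02 ± 1.19 CPM. Genes in both of the authors' tables were CG15263, CG6788 and Dso1, 3 in all, each with the same sign under both treatments. All 14 of the 15 genes tested here kept the sign with an unadjusted p under 0.05, and 10 did not overlap between classes. As these genes too had been picked on the same lines, the agreement adds no separate evidence.

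In edgeR 0 of 13877 genes passed, with 611 at an unadjusted p under 0.05 and a smallest adjusted p of 0.513 (CG10962). limma-voom gave 0 with 599, and DESeq2 gave 11, 2 higher and 9 lower. Antimicrobial peptides and immune effectors had a median of −0.77 in beneficial lines (camera adjusted p = 1.65e-11, and adjusted p = 0.0959 with an estimated correlation), and 3 of 38 were lower adjusted over the list alone. Turandot and JAK-STAT genes (−0.39) and immediate early and JNK genes (−0.18) also passed camera, with the same adjusted p = 0.0959 with an estimated correlation. So did insulin and TOR genes (−0.13), mitochondrially encoded genes (−0.45), proteasome genes (0.09), gut digestive enzymes (0.22), hemocyte markers (−0.35), muscle markers (−0.19), chaperones (−0.12), neuronal markers (−0.14) and cytosolic ribosomal proteins (−0.08), 12 lists in all. None of these 9 passed with an estimated correlation (adjusted p = 0.115 to 0.961). By line scores 0 lists passed. Turandot and JAK-STAT genes stood at 3.80 ± 0.28 against 4.34 ± 0.13 log2 CPM, immediate early and JNK genes at 4.29 ± 0.10 against 4.49 ± 0.07 and proteasome genes at 6.03 ± 0.04 against 5.91 ± 0.04. For these 3 lists the classes did not overlap (exact permutation p = 0.00794, adjusted p = 0.0873). The antimicrobial score was 2.43 ± 0.36 against 3.05 ± 0.23 (exact permutation p = 0.0159, adjusted p = 0.105). RAL409, the beneficial line left out, had an antimicrobial score of 3.73, above each of the other 9 lines.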

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

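In this part, the tests of leaving out a line for the authors' genes, of depth and steadiness for RAL409, of scaling by library totals, and of splits by genes at an unadjusted p were chosen only after the result was seen, and the RAL409 pattern itself was picked after its list scores had been seen.

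Of 300 groups of 4 or 5 libraries examined, 15 held a library far from the rest, and chance gives about 1 in 20 groups, or 15. With heat shock RAL304 stood apart for 4 copies of the Hsp70B cluster. Hsp70Ba reached 8910 CPM against 4090 to 4680 in the other detrimental lines, Hsp70Bb 16000 CPM, Hsp70Bbb 14400 CPM and Hsp70Bc 14800 CPM. Hsp70 took 6.86% of its counts, against 4.13% to 4.77% in the others. Its Hsp70Aa lay within their range, at 12430 against 9596 to 12610 CPM. Its Kdm5 stood at 141 CPM against 104 to 106 CPM. RAL335 had Hsp26 at 7760 CPM and RAL387 a chaperone share of 8.93%, each the highest of its class with heat shock. RAL359 had CG12917 at 25.3 CPM with heat shock, against 11.2 to 12.3 CPM in the other beneficial lines. Hsp70Ab stood at 9690 CPM in RAL69 with heat shock, the lowest of its class, and at 12.7 CPM in RAL819 without, the highest. RAL737 had the fewest counts with heat shock, 18.4 M. Without heat shock the mitochondrial ribosomal score was 3.78 in RAL93, the neuronal score 6.79 in RAL819 and the hemocyte score 3.99 in RAL737, each apart from its class.

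The responses of 8 lists differed between the classes by camera with its preset correlation, and 0 did with an estimated one. The median of beneficial minus detrimental responses was −0.0639 for ER protein folding, −0.174 for antimicrobial peptides, −0.0795 for immediate early and JNK genes and −0.0596 for cytosolic ribosomal proteins. It was 0.0356 for the proteasome, −0.0858 for the respiratory chain, −0.098 for accessory gland markers and −0.186 for muscle markers. Line RAL409, used in no main comparison, had a chaperone share of 8.75% with heat shock and 0.399% without.

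For the gene counts, splits of the same libraries were tested. Heat shock over all lines gave 2555 genes, and 1 of 100 splits, the real one, gave as many, with 1307 the highest of the others. Among splits that part both libraries of each line, it was again 1 of 100, with 1017 the highest other. Chance can be excluded for that count. Within classes the real split was the only 1 of 35 in beneficial lines (1089 genes, highest other 78) and the only 1 of 100 in detrimental lines (1422, highest other 12), but the splits that part both libraries of each line were too few for a share under 0.05. Those others, 7 and 12, gave at most 0 genes. A real count of 0 lets no split fall below it, so for the classes without heat shock (100 of 100 splits, highest other 2), with heat shock (100 of 100, highest other 2) and for the difference between responses (100 of 100, highest other 0) these counts decide nothing. At an unadjusted p under 0.05, 59 of 100 splits gave as many as the real 576 genes without heat shock, 58 as many as the 611 with it, and 91 as many as the 42 for the difference between responses. The highest others were 1593, 1256 and 257 genes, so chance cannot be excluded for these. For the difference between responses the splits used the fit without line as a block. With the block the real classes gave 338 genes, and no splits were run on that fit.

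The class differences in the authors' tables were weighed next. With DESeq2 27 of 50 splits of the 9 lines gave as many as the real 17 genes without heat shock, with 143 the highest other, and 35 of 50 gave as many as the real 11 with heat shock, with 67 the highest other. Chance therefore cannot be excluded for these counts. Splits with several times the real count point to structure among the lines other than class, unless they are false calls of DESeq2. It made 48 and 44 in simulated class comparisons, but those held 200 changed genes. The simulated counts therefore do not give the number of false calls to expect in these splits. Whether a single line lies behind the class differences stays open. After a line was left out, 2.78% of 36 entries had p of 0.05 or more in edgeR (CR30409, for 5 of the lines, highest at 0.145 without RAL387). The count filter that had left 3 entries untested was not used here. These genes had been picked on the same lines, so a low share excludes nothing. A biological difference between the classes remains open.

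Genes scarcely read without heat shock rose with it: 194 genes below 1 CPM passed, 149 of them higher in each of the 9 lines. Muc18B (6.26 ± 0.67) and spdo (5.07 ± 0.40) were among them, both chosen after their values were seen. Genes this scarce can pass the count filter through the heat shock libraries alone, which favours rises. Read-through from an upstream gene may account for part of the 194. Within 10 kb 17% of them had a more abundant upstream riser, against 6.07% of 1416 uncalled genes (Fisher's exact p = 1.12e-06). The uncalled genes were also below 1 CPM without heat shock, but were not matched further on abundance. Cp18 with CG6511 and Cp19 with Cp18 were among them. Most had no such riser (95% interval up to 23.1%), but read-through from farther away or from a gene that did not itself rise was not tested. Reads from a gene on the other strand could account for 10.8% of them (95% interval up to 16.1%), against 4.31%. Scaling is too small a shift to explain them, with a median of −0.19 on library totals against a smallest rise of 0.62, and for that reason 100% kept a change above 0 there. Heat shock itself stays open as the cause for the rest, as a hypothesis.

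In RAL409 without heat shock the score of histone methyltransferases, the study's theme, was 4.12 against 4.53 ± 0.04 in the other 9 lines (SD, range 4.44 to 4.58). The shift was not particular to this list. Among others, the Polycomb and PHO list and neuronal markers also lay below every other line, by 0.51 and 0.67 from the mean of the others. Respiratory chain genes and mitochondrial ribosomal proteins lay above every other line, by 0.48 and 0.41 from that mean. The library had 25.23 M counts, within the range of the others, so low depth is not the cause. A steady difference of the line is not either, as with heat shock the score differed from the others by −0.00633. A trend with gene length could account for it: lists matched on exonic length and expression had a median deviation of −0.26 (−0.42 to −0.13), the list's −0.40 lay at percentile 4.5 of them, and expression fell by 0.20 on the log2 scale per doubling of length in that library, against a rise of 0.15 at the other extreme, in RAL359 with heat shock. No biological explanation was tested.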

How the results depend on the processing

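Scaling by library totals only and DESeq2 on every row with a count were chosen after the results were seen. Across the settings 0 values of called genes reversed among the 44 genes followed for heat shock over all lines. A reversal was counted only for genes called in the main fit. None of the 33 and 34 genes followed for the classes had such a call, so the count says nothing about them. Other list members and the responses within classes were not followed. The classes without heat shock gave 0 genes in edgeR but 17 with DESeq2 and 22 with it on every row. Under heat shock they gave 0 but 11 and 12. DESeq2 made 48 and 44 false calls in the simulated class comparisons, against 8 and 4 for edgeR. Those simulations held 200 changed genes, so their false calls are not the number to expect among the real calls. Heat shock over all lines gave 2555 genes, 5032 with line as a block, 5302 with line as a random effect and 4932 on library totals. Beneficial lines gave 1089, and 2767, 3136 and 2178. Detrimental lines gave 1422, and 3265, 3464 and 3443. Both fits with line remove the spread between lines (correlation of a line's libraries 0.63). Leaving out each line gave 2077 to 2338 genes over all lines, 628 to 1117 in beneficial lines (682 without RAL359) and 936 to 1419 in detrimental lines, with fewer libraries tested. For the classes and the difference of responses it gave 0 throughout.

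Lists passing camera fell from 11 to 0 for the classes without heat shock and from 12 to 0 with it, under an estimated correlation and by fry alike, and from 8 to 0 for the difference of responses. For heat shock 4 lists passed over all lines, 2 with an estimated correlation and 8 by fry. In beneficial lines 2 of 4 and in detrimental lines 1 of 4 kept the call with an estimated correlation. Of 880 values for named genes under heat shock, 5 lost the call (Ire1, trx) and 9 gained it (Atf6, Utx, ash1, crc). Apart from those given beside the results, line as a block changed no other call of a named gene. For the classes 16 values, all by DESeq2, gained it. The other settings left the counts within 1.5 times.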

Other observations

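In this part the tests of list scores between pools were written before their results were seen, and the remaining values were looked up after the results were seen.

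Line RAL409, left out of the main comparisons, differed from the other 9 lines in both libraries. It had 16 genes at least 2-fold above and 42 at least 2-fold below, where other lines had 8 to 20 above and 3 to 37 below. FANCI, a DNA repair gene, stood at 99.4 CPM without and 76.4 CPM with heat shock, against at most 10.6 CPM elsewhere. The immune peptide gene BomT3 stood at 3.09 and 3.70 CPM against at least 38.8 CPM, and CR33319 at 0.0763 and 0.0342 CPM against at least 19.5 CPM. IBIN, on the same immune list as BomT3, went the other way, at 7.02 and 4.93 CPM against at most 1.61 CPM. The score of that list was the highest of all lines in both RAL409 libraries, 0.84 and 0.96 above the mean of the others. CG6788, a gene of the authors' tables, stood at 25.8 and 28.9 CPM against at most 7.88 CPM. These genes were chosen after their values were seen.

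Hsp22, a mitochondrial small heat shock protein gene, had 0 counts in all 20 libraries. In the annotation it lies at 3L 9372931 to 9374964, inside CG4456 on the same strand (9372722 to 9374964), which had 8203 counts. Of 405 protein-coding genes at 0 in every library 325 (80.2%) lay inside another gene on the same strand, against 4.02% of 13478 with a count. Among protein-coding genes 8.3% of those that rose with heat shock had no intron, 11.3% of those that fell and 14.7% of those not called, with median exonic lengths of 2861, 2075 and 1699 bases.

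A hypothesis was that the lower immune and mitochondrially encoded scores of beneficial lines could reflect the state of single pools of flies, in which case the pools of a line should not resemble each other. Across 9 lines the immune score with and without heat shock had a Pearson r of 0.646 (permutation p = 0.0611, adjusted p = 0.0907) and a Spearman rho of 0.583 (permutation p = 0.106), and r was 0.317 without the 2 lines farthest from the median, so it rests on those. For mitochondrially encoded genes r was 0.6 (permutation p = 0.0907, adjusted p = 0.0907) and rho 0.683 (permutation p = 0.0505), with 0.537 without those 2. With 9 lines these values leave pool and line open. The class differences kept at least 70.2% of their size when a line was left out, the least for the immune score without RAL304. These lists had been picked on the same lines, so a high share was likely and does not exclude a part played by a single line. RAL409, classed as beneficial but left out here, had the highest immune score of all lines. It stood at 3.85 without and 3.73 with heat shock, against at most 3.64 and 3.43 in the other 9 lines. The lower immune score of beneficial lines thus did not extend to RAL409.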
